A study of Homo sapiens with 24 samples.

How the data were processed

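Ribosome profiling counts the stretches of messenger RNA that ribosomes protect from nuclease, so each count is a footprint of a ribosome at work on a message. Here it was applied to biopsies of human skeletal muscle taken before and after milk or cheddar cheese was eaten. The samples were 24 libraries from 4 participants, who each came for 2 visits, 1 for each food. Each visit gave 3 biopsies, at 0, 60 and 180 min, and 2 of the 4 participants had milk first. This makes 6 groups of food and time with 4 libraries each. There was no visit without food.

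The deposited tables give counts, with no normalization, of footprints on each RefSeq coding sequence. They hold 26485 rows per food, of which 9012 have a coding length of 0 and no counts, and 11590 have no count in any library. The lengths are multiples of 3 in 99.8% of rows and are therefore coding lengths. The submitters' processing notes name Bowtie, edgeR and the hg38 build, without versions. The rule for reads that fit several genes is not stated. RPS18, HBA1 and HBA2, which have near-identical copies in the genome, have 0 counts, so values for genes with close copies or pseudogenes may miss footprints. A second deposited table gives the authors' log2 fold change for 7 comparisons, and for each the authors' p-value adjusted as a false discovery rate, from edgeR's likelihood ratio test. The seventh of these is headed like the fifth, and is taken up below under the authors' own calls.

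Symbols were used as the files give them. Some are older names (current ones in NCBI's table follow): GNB2L1 is now RACK1, GLTSCR2 is NOP53, ATP5G2 is ATP5MC2, ATP5I is ATP5ME, GUCY1A3 is GUCY1A1 and KIAA0922 is TMEM131L. Of the symbols, 1197 stand on more than 1 row, and there the row with the most counts carried the symbol. The lower rows stayed in the data as separate genes but could not be named. The same holds for 31 rows that carry a date in place of a symbol and 27 that read HLA only. Another 108 rows of sex-linked genes were left out. Gene positions came from GENCODE release 29 on the same build, where all 192 named genes were found, 7 of them through an older symbol in NCBI's gene table.

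Total counts ran from 3190121 to 7444324 per library, with a median of 5537507. The labels name no molecular identifiers, so counted fragments may include PCR copies, and counting error is a lower bound on the error of a value.

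Counts were analysed in edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes passed edgeR's expression filter with its minimum count of 10, which left 10170. TMM factors scaled the libraries, and a quasi-likelihood fit of the 6 groups over all 24 libraries gave each comparison. A gene was called at an adjusted p (Benjamini-Hochberg) of 0.05. The 11 comparisons were each food at 60 and 180 min against 0 min, the average of both foods at each time, the foods against each other at each time, and the difference between the foods in the change by 60 and by 180 min. The comparisons, tests, alternatives and named genes were fixed before the data were examined, except where the text says otherwise. All p-values are two-sided. Fold changes are on the log2 scale and given with their standard error (SE). Levels are CPM, counts scaled to a common library total by the TMM factors, with their standard deviation (SD), n = 4 libraries.

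The labels number the participants, and those numbers pair the libraries. As a check, correlations across genes were taken after the group means were removed. The median was 0.37 between libraries of 1 participant and -0.13 between participants. Removing the means makes the values between participants negative when those within are positive, so -0.13 is no separate evidence. All 24 libraries had their highest mean correlation with the libraries of their own participant in other groups. The fit fixed in advance leaves the participant out. A fit with the participant as a block lowered the common biological coefficient of variation from 0.218 to 0.132, and left 15 residual degrees of freedom in place of 18. Its counts stand beside those of the fit without it. This block leaves the visit out, though the same correlation had a median of 0.45 within a visit and 0.35 between the visits of a participant. Its counts between the foods at a single time may therefore include differences between visits. Within groups, no pair of libraries was a technical repeat: over 36 pairs, chi-square per degree of freedom was 13.4 to 57.3.

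Gene groups were 31 lists written before the data were examined, covering translation, nutrient and hormone signalling, metabolism, the contractile apparatus, stress and other cell types. The 29 with at least 3 tested members were compared with all other genes by camera on voom values, with a preset correlation of 0.01, and p-values were adjusted over 319 tests. Of the 61 calls, 4 held when camera estimated the correlation from the data: the ribosomal protein list and the list of translation factors and other 5' TOP messages, each at 60 min after milk and at 60 min over both foods. TOP messages carry a terminal oligopyrimidine tract through which mTORC1 signalling controls their translation. For the lists treated at length, counts of members are given over all genes tested and adjusted over the list alone.

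Genes were named by a fixed rule. For each comparison against 0 min it took the 12 smallest p-values in each direction among genes with a mean of at least 4 CPM; where fewer than 20 genes were called, it took all of those, then genes called with the participant block. Between foods it took 6 per direction. It added up to 4 members of each list past the threshold over the list alone, and 17 genes reported whatever they showed.

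The fit was tested on simulated counts, drawn from the means, participant effects, library sizes and dispersions fitted to these libraries, with 67, 67 and 66 genes changed by 1.5, 2 and 3-fold in the comparison of milk at 60 min with 0 min, over 10070 genes. Without the block, 19.4%, 65.7% and 92.4% of these were recovered, with 1 false call among 119. With the block, 49.3%, 83.6% and 100% were recovered, with 6 false calls among 161. The simulated counts held no effect of the visit and the same fold in each participant, as the block fit assumes. They favour that fit, so its recovery and false calls may not carry over to the data.

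Alternatives were the participant as a block, the visit as a block, the block with the visit number, DESeq2 1.42.0 with and without the block, voom with the participant as a random effect, DESeq2's type of size factors in edgeR, library totals alone, no filter, a stricter filter of 5 CPM in 4 libraries, haemoglobin and mitochondrial genes left out, the compared groups alone, a robust fit, an adjusted p of 0.1, and each participant left out. Translation efficiency was not computed, since the labels mention RNA sequencing but the deposited count tables hold footprints alone. Tables were handled with Python 3.11.15 and pandas 2.3.3 and drawn with matplotlib 3.10.9.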

Results

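Footprints were counted in 24 libraries of human skeletal muscle, 4 at each of 0, 60 and 180 min after milk and after cheddar cheese. Total counts per library ran from 3190121 to 7444324, with a median of 5537507. The series is about anabolic effects of cheddar cheese in muscle, and its design asks how ribosome occupancy in muscle responds to each food, and whether it responds alike to both. Without a visit without food, a change from 0 min holds for the time after the food, including the earlier biopsies and the hour of the day. The comparisons between foods have the same biopsies on both sides, but the labels do not give the hour or fasting state of the visits.

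At 60 min after milk, footprints rose on nearly all ribosomal protein messages and on 16 of 27 translation factors and other 5' TOP messages. Of 77 cytosolic ribosomal protein genes, 73 rose over all genes tested and 77 when adjusted over the list alone, with a median log2 fold change of 1.84 (3.57-fold). Their share of all counts went from 0.395% ± 0.046 (SD, n = 4) at 0 min to 1.22% ± 0.33 at 60 min, higher in 4 of 4 participants (exact sign-flip test, p = 0.125, the smallest that 4 participants can give). RPL14 went from 62 ± 10.5 to 245 ± 44.5 CPM (log2 1.98, SE 0.21, adjusted p = 5.33e-06) and RPL30 from 93 ± 13.8 to 483 ± 157 (log2 2.38, SE 0.25, adjusted p = 5.33e-06). By camera the list had an adjusted p of 8.36e-213, and an adjusted p = 0.00525 with an estimated correlation.

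**Figure D1:**
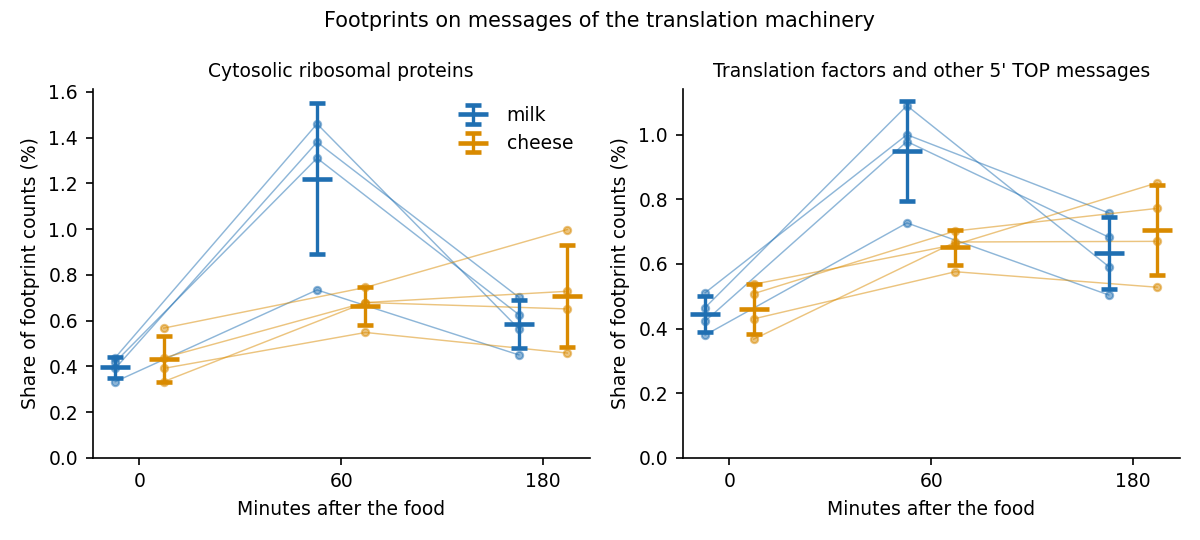
Share of all footprint counts (vertical axis, percent) on ribosomal protein messages (left) and on translation factors and other 5' TOP messages (right) at 0, 60 and 180 min after milk (blue) or cheese (orange). Thin lines join the 3 biopsies of a visit, thick marks give the mean and bars the SD of 4 libraries. The ribosomal protein share after milk has a mean of 1.22% at 60 min and 0.585% at 180 min, and after cheese 0.663% and 0.709%.

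Of 27 translation factors and other 5' TOP messages, 16 rose after milk at 60 min, and 23 when adjusted over the list alone (median log2 0.94, camera adjusted p = 1.37e-55, adjusted p = 0.00525 with an estimated correlation). EEF2, which moves the ribosome along the message, had the largest change of all genes called: 283 ± 92.1 CPM at 0 min and 1820 ± 619 at 60 min (log2 2.68, SE 0.39, adjusted p = 8.27e-05). EIF3F, EIF3E and EIF3H, subunits of an initiation factor, rose by log2 1.42, 1.06 and 1.07, and GNB2L1, a ribosome-bound scaffold protein, by 1.72. GLTSCR2, a nucleolar protein of ribosome assembly outside the list, rose by 1.88. EEF2 and these 5 genes were higher in 4 of 4 participants. PABPC1 (log2 0.84, adjusted p = 0.136) and EEF1A1 (log2 0.73, adjusted p = 0.552) did not pass in the fit without the participant block. Both passed in the authors' likelihood ratio test, with log2 0.88 and 0.75 and a false discovery rate of 2.91e-05 and 0.0137. EEF1A1 has close copies in the genome, and whether its count misses footprints was not tested.

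Beyond translation, a few abundant muscle messages rose after milk at 60 min. In the list of sarcomere and cytoskeleton genes, 4 of 27 rose, and 6 when adjusted over the list alone. CKM, the muscle creatine kinase, went from 17800 ± 3260 to 50900 ± 6670 CPM (log2 1.52, SE 0.24, adjusted p = 0.000204). DES, the intermediate filament desmin, rose by log2 1.40, KLHL41, a sarcomere-associated protein, by 1.27 and ACTA1, skeletal actin, by 0.75. The list's median was 0.12, with camera adjusted p = 2.3e-05 and adjusted p = 0.733 with an estimated correlation. Among 24 genes of glycolysis and glycogen, GAPDH (log2 1.15) and ENO3 (1.05) rose, 4 when adjusted over the list alone (camera adjusted p = 0.00555, adjusted p = 0.988 with an estimated correlation). ATP5G2, of ATP synthase, rose by 0.80. The 22 immediate early genes, transcription factors and others induced within minutes, had a median of 0.66 with 0 called by edgeR over all genes and 1 over the list alone (camera adjusted p = 0.0482, adjusted p = 0.988 with an estimated correlation). The share of the immediate early list was higher in 3 of 4 participants, and its camera call ended without at least 1 participant. Its member FOS had 109 CPM in 1 library at 60 min, against 2.61 to 8.99 in the others. The myosin heavy chains MYH7 (log2 0.11, adjusted p = 0.999) and MYH2 (-0.05, adjusted p = 0.999) did not pass. IBTK, an inhibitor of a tyrosine kinase (log2 -1.0, adjusted p = 0.00137), IRF2 (-0.65, adjusted p = 0.00713), an interferon response factor, and SLC38A10 (-0.80, adjusted p = 0.0401), an amino acid transporter, were the 3 genes that fell, each in 4 of 4 participants.

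In all, 136 genes changed at 60 min after milk by edgeR, 133 up and 3 down, and with the participant as a block 226 rose and 16 fell, with all 136 among them. Scaled by library totals alone, the median of all genes lay at log2 -0.22 and 103 genes rose and 17 fell, so the small number of falling genes depends on the scaling. Leaving out replicates A, B, C or D ended at least 1 call among IBTK, DES, ACTA1, KLHL41, IRF2, GAPDH, ENO3, ATP5G2 and SLC38A10, and the other 16 genes named as called passed each time.

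At 60 min after cheese the same translation lists lay higher, by less. The ribosomal protein genes had a median log2 fold change of 0.73 (1.66-fold): 0 of 77 rose over all genes tested, 62 when adjusted over the list alone, and 39 with the participant block. Their share of counts was 0.432% ± 0.10 at 0 min and 0.663% ± 0.083 at 60 min, higher in 4 of 4 participants (exact sign-flip test, p = 0.125). RPL14 stood at 66.6 ± 16.1 and 130 ± 15.5 CPM (log2 0.96, SE 0.21, adjusted p = 0.518; 0.011 with the block). EEF2 stood at 349 ± 114 and 792 ± 174 (log2 1.18, adjusted p = 0.809; 0.015 with the block). By camera, adjusted p was 1.55e-87 for the ribosomal proteins, and adjusted p = 0.0936 with an estimated correlation. For the 27 TOP messages (median 0.49, 18 past the threshold over the list alone) it was 2.83e-34, and adjusted p = 0.0504 with an estimated correlation.

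Camera called 6 other lists at 60 min after cheese. The 20 glucocorticoid targets had a median of 0.36 (camera adjusted p = 8.78e-05, adjusted p = 0.429 with an estimated correlation); FKBP5, a co-chaperone of the glucocorticoid receptor, stood at 14 ± 4.62 and 36.9 ± 9.93 CPM (log2 1.41, SE 0.29, adjusted p = 0.518; 0.0071 with the block) and TXNIP, a brake on glucose uptake, at log2 1.26. The share of this list was higher in 4 of 4 participants, but 1 library at 60 min stood at 0.856%, against 0.398% to 0.631% in the others. It is the library that also carried the immediate early genes. The 22 immediate early genes had a median of 1.39 (camera adjusted p = 2.62e-05, adjusted p = 0.988 with an estimated correlation), with FOS at log2 5.47, EGR1 at 4.81 and JUNB at 3.04. These values came from 1 library, which had 496 CPM of FOS, against 1.42 to 2.87 in the 3 others, 350 of EGR1, against 1.73 to 6.07, and 149 of JUNB, against 4.47 to 6.14. The whole list took 0.293% of its counts, against 0.0318% to 0.0583% in the others at 60 min and 0.034% to 0.0555% in the 4 libraries at 0 min. Lists of extracellular matrix genes (median -0.31, camera adjusted p = 2.84e-05) and smooth muscle markers (-0.34, 0.00585) lay lower, with adjusted p = 0.988 and adjusted p = 0.609 with an estimated correlation, and the fast fibre (0.19, 0.00382) and sarcomere (0.09, 0.0128) lists higher, both with adjusted p = 0.988 with an estimated correlation. The matrix share of counts went from 0.603% to 0.293% in 1 participant, while the 3 others had 0.372% to 0.470% at 0 min and 0.351% to 0.472% at 60 min. The smooth muscle share, which includes DES, was higher at 60 min in 3 of 4 participants (0.527% ± 0.07 and 0.619% ± 0.12), against the sign of the list's median.

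By edgeR 0 genes changed at 60 min after cheese, with 341 at an unadjusted p under 0.05. The block gave 636 under 0.05, where chance gives 508. A count below 508 without the block is no sign of absent change, since that fit takes differences between participants as error. With the participant block 52 rose and 1, NR2F2, fell (log2 -0.61). DESeq2 without the block called 14 genes and voom with the participant as a random effect 21. With the block, leaving out replicates A, B, C and D in turn gave 1, 39, 3 and 63.

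**Figure D2:**
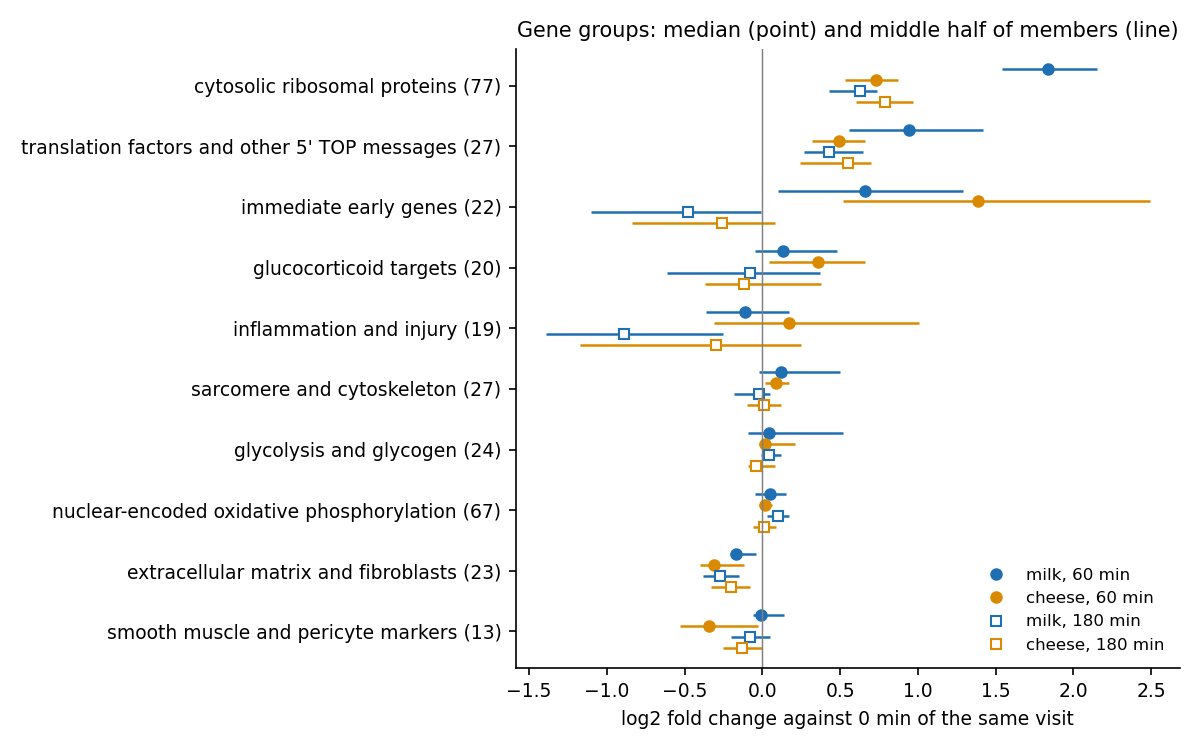
Median log2 fold change against 0 min (horizontal axis) of 10 gene groups, with the number of tested members in brackets, after milk (blue) and cheese (orange) at 60 min (filled circles) and 180 min (open squares); lines run from the lower to the upper quartile of the members. The ribosomal proteins stand apart after milk at 60 min, with a median of 1.84 against 0.73 after cheese.

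Averaged over both foods at 60 min, 136 genes rose and 2 fell (257 and 23 with the participant block). Scaled by library totals alone the split was 108 and 30. Of the 77 ribosomal protein genes 73 rose, 76 when adjusted over the list alone (median 1.31), and of the 27 TOP messages 19 rose, 23 over the list alone, now with PABPC1, the poly(A)-binding protein (log2 0.91, adjusted p = 0.0024). Further genes rose at 60 min: KLF10, an early transcription factor (log2 2.15, SE 0.38, adjusted p = 0.000924), FKBP5 (1.10, adjusted p = 0.00179), TXNIP (1.19, adjusted p = 0.0033), SHMT2, of mitochondrial serine metabolism (0.47, adjusted p = 0.0146), and MYOD1, the myogenic regulator (1.04, adjusted p = 0.0224), each in 4 of 4 participants. IBTK (log2 -0.50, adjusted p = 0.0403) fell in 4 of 4. FOS (4.25, adjusted p = 0.025), EGR1 (3.86, adjusted p = 0.0215) and JUNB (2.46, adjusted p = 0.0377) passed as well. Those 3 calls ended when any of the 4 participants was left out, and without replicate D the values were 1.86, 1.45 and 1.12. The named calls of KLHL41, TXNIP, DES, ACTA1, SHMT2, MYOD1, ATP5G2, GAPDH and IBTK ended without at least 1 participant.

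Other lists called over both foods at 60 min were the sarcomere list (4 of 27 rose, 5 over the list alone, median 0.08, camera adjusted p = 1.84e-05, adjusted p = 0.733 with an estimated correlation) and the glucocorticoid targets (2 of 20 rose, 5 over the list alone, median 0.30, camera adjusted p = 0.00142, adjusted p = 0.671 with an estimated correlation). Of the immediate early genes 4 of 22 rose, with 9 up and 1 down over the list alone (median 0.96, camera adjusted p = 0.000218, adjusted p = 0.988 with an estimated correlation), a value that includes the cheese library described above. Glycolysis and glycogen (1 of 24 rose, median 0.03, camera adjusted p = 0.00543) and the fast fibre list (0 of 16 rose, median 0.08, camera adjusted p = 0.00345) lay higher, and the extracellular matrix list (0 of 23 fell, median -0.20, camera adjusted p = 0.000739) lower. These 3 had adjusted p = 0.988 with an estimated correlation. The matrix call ended without replicate D, whose share after cheese went from 0.603% at 0 min to 0.293% at 60 min.

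At 180 min, the data of both foods together showed changes in further genes beside a smaller rise of the ribosomal protein and TOP messages. IRS1, the adaptor that carries the insulin signal, fell from 54.6 ± 14 to 22 ± 5.04 CPM after milk and from 60.3 ± 13 to 21 ± 1.49 after cheese (log2 -1.42 over both foods, SE 0.14, adjusted p = 7.11e-06). FKBP5 rose (log2 1.62, SE 0.20, adjusted p = 0.000111), and PABPC4, a poly(A)-binding protein, rose by 0.81 (adjusted p = 7.11e-06). ARID5B, a chromatin protein, fell by 1.73 on the log2 scale (SE 0.18, adjusted p = 7.11e-06). NFKBIA, the inhibitor of NF-kappaB, had log2 -1.11 (SE 0.15, adjusted p = 0.000184) and DUSP1, a MAP kinase phosphatase, -1.42 (adjusted p = 0.000529). GADD45G (-1.84), BCL6 (-1.22), E2F8 (-1.15), VGLL4 (-1.05), IRF2BP2 (-1.21), SEMA6D (-0.96), PIK3IP1 (-0.90) and KIAA0922 (-0.65) fell as well. PDE4B, a cyclic AMP phosphodiesterase (0.93), SRSF5, a splicing factor (0.75), and PLEKHH3 (0.57) rose. Each of these had its direction in 4 of 4 participants.

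Grouped by list at 180 min over both foods, 3 of 20 clock genes fell: NR1D1, a repressor of the clock (log2 -1.56, adjusted p = 0.0122), CIART (-0.84) and PER1 (-0.62), with 5 over the list alone. The list had a median of -0.16 (camera adjusted p = 0.03, adjusted p = 0.609 with an estimated correlation). Of 30 genes of the atrophy and FOXO list, TRIM63, a muscle ubiquitin ligase (-0.69, adjusted p = 0.0209), and BCL6 fell and FOXO1 rose (0.93, adjusted p = 0.0222). FBXO32, the other ligase, stood at -0.70 (adjusted p = 0.217; 0.0078 with the block), and SLC38A2, an amino acid transporter, at -0.34 (adjusted p = 0.505). The 19 inflammation and injury genes had a median of -0.79, with NFKBIA and OTUD1 (-2.19) down, and 6 down and 1 up over the list alone (camera adjusted p = 0.00156, adjusted p = 0.733 with an estimated correlation). Among 22 immediate early genes DUSP1 and IER5 (-1.01) fell and KLF10 rose (1.61), with 7 down and 1 up over the list alone. The median was -0.40 (camera adjusted p = 0.00604, adjusted p = 0.988 with an estimated correlation). In the myogenic list of 18, MYOD1 rose (1.19). HK2, muscle hexokinase, stood at log2 1.03 (adjusted p = 0.091; 0.00043 with the block), and MT2A at -0.15 (adjusted p = 0.97). The 23 extracellular matrix genes had a median of -0.24 with 0 called by edgeR, over all genes or over the list alone. Camera gave adjusted p = 0.000124, and adjusted p = 0.988 with an estimated correlation. This camera call ended without replicate D, whose matrix share after cheese went from 0.603% at 0 min to 0.303%. The share was higher at 180 min in 0 of 4 participants after milk and 1 of 4 after cheese.

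Ribosomal protein genes lay above their 0 min level at 180 min after both foods: 38 of 77 rose, 73 when adjusted over the list alone and 70 with the participant block (median 0.71, camera adjusted p = 2.48e-74, adjusted p = 0.144 with an estimated correlation). Of the 27 TOP messages 13 rose, 20 over the list alone (median 0.50, camera adjusted p = 5.7e-31, adjusted p = 0.0626 with an estimated correlation). EEF2 rose by log2 1.32 (adjusted p = 0.0107). In all, 76 genes rose and 43 fell by edgeR, 237 and 160 with the participant block. Leaving out replicates A, B, C and D gave 38, 20, 16 and 141 genes without the block, and 293, 263, 201 and 312 with it. IRS1, PABPC4, ARID5B, FKBP5, NFKBIA, IRF2BP2, PLEKHH3, RPL14, GADD45G, KIAA0922 and PDE4B passed each time, and the other 24 named calls ended without at least 1 participant. One milk library at 0 min held a larger share of leukocyte marker counts than the other 23, 0.133% against at most 0.0641%; without it 77 genes changed.

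**Figure D3:**
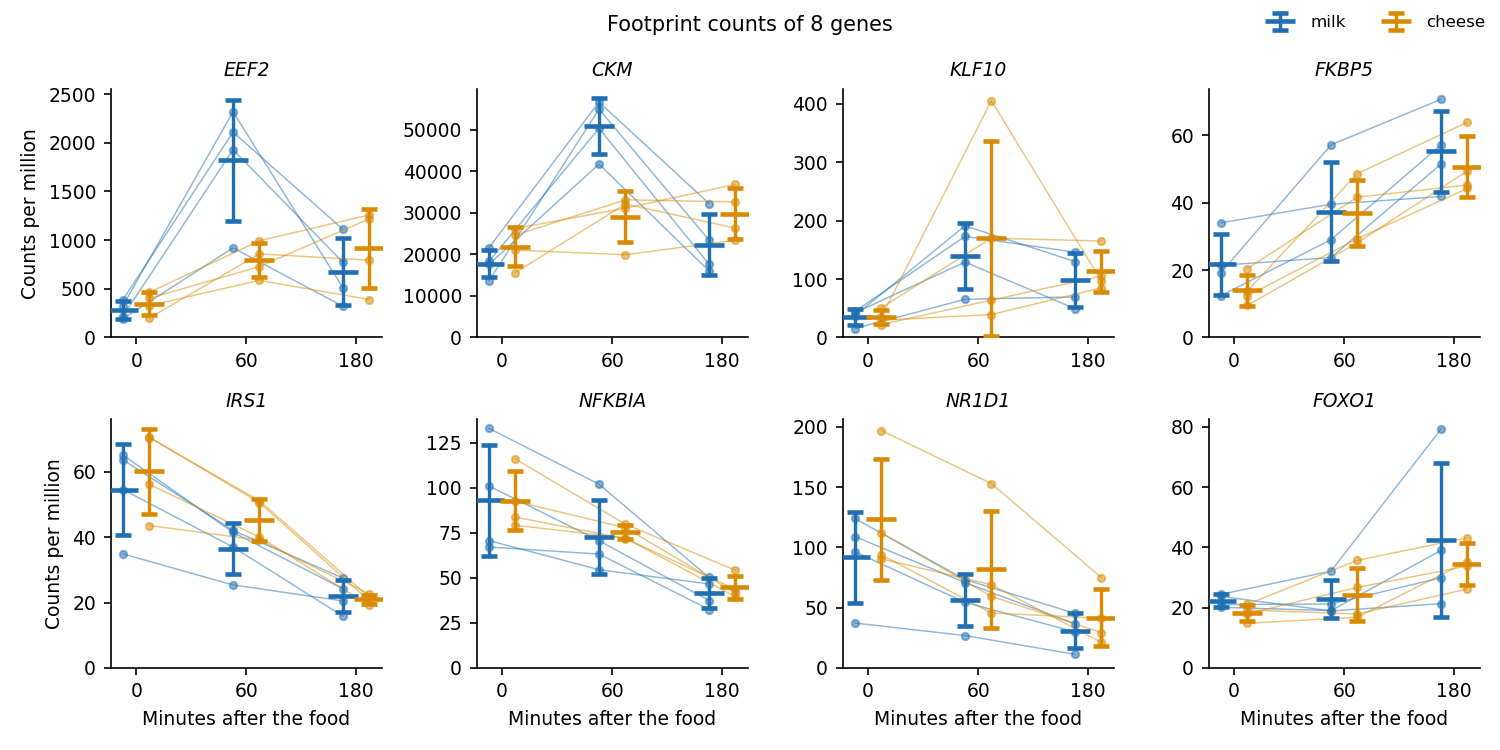
CPM (vertical axis) of 8 genes at 0, 60 and 180 min after milk (blue) or cheese (orange). Thin lines join the 3 biopsies of a visit, thick marks give the mean and bars the SD of 4 libraries. EEF2 and CKM have their highest means at 60 min after milk, IRS1 and NFKBIA have their lowest at 180 min after both foods.

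Taken by food at 180 min, the calls were few. After milk 3 genes rose and 5 fell: PABPC4 (log2 0.91, adjusted p = 0.00113), PDE4B (1.16) and PLEKHH3 (0.64) up, and ARID5B (-1.79), IRS1 (-1.31), NFKBIA (-1.17), DUSP1 (-1.58) and IRF2 (-0.73) down. After cheese 3 rose and 5 fell: FKBP5 (log2 1.87, adjusted p = 0.00487), PABPC4 (0.70) and RPL14 (1.17) up, and IRS1 (-1.52, adjusted p = 0.00123), ARID5B (-1.67), IRF2BP2 (-1.32), GADD45G (-2.03) and NFKBIA (-1.05) down. Each had its direction in 4 of 4 participants. With the participant block the counts were 65 up and 52 down after milk, and 121 up and 46 down after cheese. The block added NR1D1 after both foods (-1.56 and -1.57) and the ribosomal proteins in part, 27 of 77 after milk and 58 after cheese. Without replicates A, B, C and D the unblocked counts were 2, 1, 2 and 13 after milk and 2, 1, 2 and 53 after cheese, and with the block 40, 11, 44 and 145, and 54, 60, 63 and 143. Without the milk library rich in leukocyte markers, 4 genes changed after milk, 52 with the block.

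Lists at 180 min were led by the ribosomal proteins after each food. After milk the ribosomal proteins had a median of 0.63 (0 rose, 48 over the list alone, camera adjusted p = 2.11e-42, adjusted p = 0.515 with an estimated correlation), and after cheese 0.79 (1 rose, 71 over the list alone, camera adjusted p = 2.67e-74, adjusted p = 0.144 with an estimated correlation). The TOP messages had medians of 0.43 after milk (camera adjusted p = 7.18e-20, adjusted p = 0.171 with an estimated correlation) and 0.55 after cheese (9.5e-30, and adjusted p = 0.0626 with an estimated correlation). After milk camera also called the immediate early (-0.48), inflammation (-0.89), extracellular matrix (-0.27) and leukocyte (-0.66) lists down and nuclear-encoded oxidative phosphorylation up (0.10), and after cheese the inflammation (-0.30), matrix (-0.20) and clock (-0.08) lists down. With an estimated correlation these 8 calls had adjusted p = 0.671 or more. The leukocyte value came from the milk library rich in these markers at 0 min: that participant's share went from 0.133% to 0.0409%, while the others had 0.029% to 0.0641% at 0 min and 0.0295% to 0.0611% at 180 min. The matrix share after cheese went from 0.603% to 0.303% in 1 participant, while the others had 0.372% to 0.470% at 0 min and 0.361% to 0.491% at 180 min.

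The comparison of the foods at 60 min asks whether muscle after cheese differed from muscle after milk at that time. Of the times sampled, it had the highest ribosomal protein share after milk. Ribosomal protein footprints were lower after cheese: all 77 genes had a lower value, with a median of -0.95, and 2 were called over all genes, 74 over the list alone and 73 with the participant block (camera adjusted p = 1.04e-100, adjusted p = 0.0626 with an estimated correlation). The 5 genes called by edgeR were GLTSCR2 (log2 -1.33, SE 0.20, adjusted p = 0.00785), RPS13 (-1.01, adjusted p = 0.0442), RPL23A (-0.71, adjusted p = 0.0442) and YBX3, a cold-shock RNA-binding protein (-0.88, adjusted p = 0.0442), lower in 4 of 4 participants, and IBTK (1.10, adjusted p = 0.017), higher in 4 of 4. With the block 6 were higher and 116 lower, among them EEF2 (log2 -1.20, adjusted p = 0.328; 0.0052 with the block). Leaving out replicates A, B, C and D gave 0, 0, 0 and 79 genes without the block and 81, 88, 73 and 128 with it. The block leaves the visit out, so its counts here may include differences between visits beside the food. The TOP messages had a median of -0.35, with 12 lower and 1 higher over the list alone (camera adjusted p = 2.75e-17, adjusted p = 0.232 with an estimated correlation). The branched-chain amino acid breakdown (0.18), oxidative phosphorylation (0.12) and leukocyte (-0.29) lists were also called by camera, with adjusted p = 0.772 or more with an estimated correlation.

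Before the food, the comparison of the visits gave 0 genes by edgeR, with 388 at an unadjusted p under 0.05. With the participant block 855 lay under 0.05, where chance gives 508. That block leaves the visit out, and libraries of a visit vary together, so the 855 may include ordinary spread between visits. The fit without the block takes differences between participants as error, so its 388 cannot be set against 508. DESeq2 without the block and voom with the participant as a random effect also called 0. EdgeR with the block called 2, among them USP6 (log2 -1.76), and DESeq2 with the block called 15. The 17 leukocyte markers had a median of -0.80 before cheese against before milk (camera adjusted p = 2.84e-05, adjusted p = 0.988 with an estimated correlation). Without the milk library rich in these markers the median was -0.20. Ribosomal proteins (0.17), oxidative phosphorylation (0.15), extracellular matrix (0.12) and smooth muscle (0.12) were called up by camera. Each had adjusted p = 0.733 or more with an estimated correlation. The matrix call ended without replicate D, whose share before cheese was 0.603%, against 0.372% to 0.47% in the other libraries before cheese. The ribosomal protein and smooth muscle calls each ended without at least 1 participant. At 180 min 0 genes differed by edgeR, with 184 at an unadjusted p under 0.05, and 0 by DESeq2, by voom with the participant as a random effect and with the block. There camera called the ribosomal proteins (0.33), the TOP messages (0.15), slow fibre genes (0.26), the matrix (0.22), sarcomere (0.10) and oxidative phosphorylation (0.08) higher after cheese, each with adjusted p = 0.988 with an estimated correlation.

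Whether the foods differed in their change from 0 min was tested directly. By 60 min every one of the 77 ribosomal protein genes had a larger change after milk, with a median difference of -1.10 (cheese minus milk). Of these, 0 passed over all genes, 71 when adjusted over the list alone and 64 with the participant block. The share of counts on these genes grew by 0.824 percentage points after milk and 0.231 after cheese, more after milk in 4 of 4 participants (exact sign-flip test, p = 0.125, the smallest possible). By camera the list had an adjusted p of 3.48e-99, and adjusted p = 0.0626 with an estimated correlation (0.0112 with the block). RPL30 (log2 -1.43, SE 0.33, adjusted p = 0.595; 0.0069 with the block), EEF2 (-1.50, SE 0.52, adjusted p = 0.924; 0.019), CKM (-1.11, adjusted p = 0.598; 0.0088) and DES (-0.90, adjusted p = 1; 0.013) had the smaller change after cheese in 4 of 4 participants. Of the TOP messages 12 of 27 passed over the list alone, all lower (median -0.46, camera adjusted p = 2.93e-18, adjusted p = 0.209 with an estimated correlation). Smooth muscle markers had a median of -0.28 (camera adjusted p = 0.00165, adjusted p = 0.429 with an estimated correlation). The sarcomere list was called down (camera adjusted p = 0.03, adjusted p = 0.988 with an estimated correlation) with a median of 0.00 and a mean of -0.15.

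Over all genes edgeR called 0 in the change by 60 min, with 272 at an unadjusted p under 0.05. With the participant block 3 genes were higher and 80 lower, DESeq2 without the block called 36 and voom with the participant as a random effect 22. With the block the count was 0 without replicate A and 0 without replicate B, 64 without C and 86 without D. The unblocked count was 8 without D and 0 without each of the others.

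By 180 min 0 genes differed between the foods in their change by edgeR, with 163 at an unadjusted p under 0.05, and 0 by DESeq2, by voom with the participant as a random effect and with the block. The ribosomal proteins had a median difference of 0.16 (camera adjusted p = 0.00114, adjusted p = 0.988 with an estimated correlation), and 7 of 77 had the larger change after milk. Oxidative phosphorylation genes had a median difference of -0.08 (camera adjusted p = 0.0356, adjusted p = 0.988 with an estimated correlation).

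Across the 10170 genes, which are not independent replicates, the change after milk and the change after cheese had a Pearson r of 0.35 at 60 min (Spearman 0.25) and 0.40 at 180 min (Spearman 0.34). Without the ribosomal protein and TOP lists r was 0.27 and 0.37.

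The genes named above lie on many chromosomes. On hg38, EEF2 spans 3976056 to 3985469 of chromosome 19, CKM 45306414 to 45322977 of chromosome 19, RPL14 40457292 to 40468587 of chromosome 3, IRS1 226731317 to 226799759 of chromosome 2, FKBP5 35573585 to 35728583 of chromosome 6, and ARID5B 61901300 to 62096944 of chromosome 10. All counts are over their coding sequences.

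The authors' own calls are in the deposited table of fold changes. At the authors' false discovery rate of 0.05, and over rows with a usable symbol, 291 genes differed at 60 min after milk, 257 of them higher, and 113 at 60 min after cheese, 106 higher. At 180 min 328 differed after milk and 262 after cheese. Between the foods 9 differed at 0 min and 113 at 60 min, 109 of the latter lower after cheese. Of the 291 genes, 136 were also called here without the participant block and 211 with it; of the 113 after cheese at 60 min, 0 and 51. None of the authors' calls had the opposite sign here, but both sets of values come from the same libraries, so this is no independent check. The seventh block of the table has the heading of the comparison at 0 min, but its values followed the comparison of the foods at 180 min in the counts (r = 0.989 across genes, against 0.223 for 0 min), and 2 genes passed in it.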

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

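Tests of leukocytes in 1 milk library, of a lower starting level before milk, of a lower share of muscle fibre, of the time of day and of injury were chosen after the results were seen. The tests of coding length, of library depth and of other splits of the libraries were planned.

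Within the groups of 4 libraries, 7 of the 144 sets of values tested had 1 library far from the other 3, by Dixon's test; chance gives about 1 in 20. A total count of 3.3 M stood apart before milk, where the others had 5.37 to 5.59 M. This was replicate D, whose libraries at 60 and 180 min after milk also held 3.19 and 3.23 M. Its cheese visit held 5.48 to 6.99 M. At 60 min its ribosomal protein share was 0.734% after milk, against 1.31% to 1.46% in the others. After cheese that share was 0.548%, against 0.679% to 0.745%. IRS2, an insulin receptor substrate, had 7.83 CPM in 1 library before milk, against 15.5 to 16.4. FOS reached 109 in 1 library at 60 min after milk, against 2.61 to 8.99, and 496 in 1 at 60 min after cheese, against 1.42 to 2.87. EGR1 reached 350 in 1 library at 60 min after cheese, against 1.73 to 6.07. SLC38A2 had 520 in 1 library at 60 min after milk, against 692 to 725, and PER1 had 167 in 1 at 60 min after cheese, against 117 to 121. The cause was not tested.

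The change from 0 min was called different between the foods in these results by at least 1 test. By 60 min the median difference (cheese minus milk) was -1.10 for the ribosomal protein list, -0.46 for the TOP messages, 0.00 for the sarcomere list, whose mean was -0.15, and -0.28 for smooth muscle markers, all by camera with the preset correlation. With an estimated correlation and no block none of these calls held: adjusted p was 0.0626, 0.209, 0.988 and 0.429 in the same order. With the participant block and an estimated correlation the ribosomal protein call passed (0.0112) and the other 3 did not (0.0514, 0.528 and 0.49). By 180 min the ribosomal proteins had 0.16 and oxidative phosphorylation -0.08, both with adjusted p = 0.988 with an estimated correlation. In the change by 60 min 83 genes differed with the participant as a block, 0 without replicate A and 0 without replicate B. Without the block edgeR called 0, with 272 at an unadjusted p under 0.05, DESeq2 36 and voom with the participant as a random effect 22.

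Ribosomal protein footprints rose more by 60 min after milk than after cheese. A bias by coding length was tested with 263 genes matched to the ribosomal protein genes on coding length (median 426 against 402 bases) and abundance: their median difference was 0.03 (quartiles -0.07 to 0.15), against -1.09 for the ribosomal proteins with the block. Library depth was tested by thinning each library to the smallest total, which gave -1.06. A lower starting level before milk was tested at 60 min directly, where the foods differed by -0.93, against 0.18 at 0 min with the block. The values for coding length and for the starting level argue against those explanations. Thinning keeps each gene's expected share of counts, so its value had to lie near -1.09 and cannot decide on library depth. Footprints shared between paralogs, the form and composition of the foods, and messenger RNA levels stay open and untested.

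Leukocyte marker footprints were lower before cheese than before milk, with a median of -0.80 over 17 markers. One milk library had 0.133% of its counts on these markers, against 0.0205% to 0.0641% in the other 23, and without it the median was -0.20. Leukocytes in 1 milk library may therefore account for most of the difference. A lower share of muscle fibre in the milk biopsies would raise the markers of the other tissues alike, and the lowest median over the endothelial, matrix and smooth muscle lists was 0.04 (highest 0.12). Whether blood or an infiltrate brought the cells stays open, and no biological explanation was tested.

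Individual genes of the clock (NR1D1, PER1, CIART), of stress responses (DUSP1, NFKBIA) and of insulin signalling (IRS1) changed by 180 min over both foods, while the insulin response and heat shock lists were not called. Injury by the earlier biopsies would raise inflammation and injury genes, whose median was -0.79 (quartiles -1.04 to -0.03). The list's share was lower at 180 min in 4 of 4 participants after each food. At 0 min the milk library rich in leukocyte markers held 0.0588% on this list, against 0.0188% to 0.0312% in the other milk libraries. An injury response in other genes was not tested, so injury is not excluded. The time of day or fasting time cannot be told apart from the food, since no visit was without food: 0 genes differed between the foods in their change by 180 min by edgeR with the block, with 326 at an unadjusted p under 0.05, and 0 by DESeq2 and voom.

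Other splits of the same libraries into groups of the same sizes were counted without the block, 35 for each comparison of 2 groups. At 60 min after milk 1 of 35, the real one, gave as many genes (136, highest other 71), at 180 min after cheese 1 of 35 (8, highest other 0), and for cheese against milk at 60 min 1 of 35 (5, highest other 4). At 180 min after milk 2 of 35 gave as many (8, highest other 14). Over both foods 1 of 100 drawn splits did so at 60 min (138, highest other 107) and 1 of 100 at 180 min (119, highest other 4). The other 5 comparisons had 0 genes by edgeR, reached by 35 of 35 splits, with a highest other of 1 for the foods at 0 min and 0 for the rest. Most of these splits mix the participants' pairs, which vary together. Among the splits that part as many pairs as the real one, the highest other was 0 in each comparison with calls except cheese against milk at 60 min, where it was 4. With 8 such splits, or 4 to 8 among those drawn, they are too few for a share under 0.05.

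With the participant as a block only 8 splits exist for a comparison of 2 groups, too few for a share under 0.05. The real counts and the highest others were 242 and 1 at 60 min and 117 and 1 at 180 min after milk, 53 and 0 at 60 min and 167 and 1 at 180 min after cheese. For cheese against milk they were 2 and 1 at 0 min, 122 and 35 at 60 min and 0 and 2 at 180 min, and for the change 83 and 0 by 60 min and 0 and 0 by 180 min. The real split was the 1 with the most genes, except at 180 min between foods and in the change by 180 min, where 8 of 8 had as many. Over both foods 1 of 100 drawn splits, the real one, gave as many genes at 60 min (280, highest other 193) and at 180 min (397, highest other 126). These splits swap the 2 visits of a participant separately. Swapping both visits together would leave too few splits for a share under 0.05, so chance is not excluded for these counts.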

How the results depend on the processing

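Leaving out the milk library rich in leukocyte markers, leaving out participants from the fit with the block, and the list tests with the block and an estimated correlation together, were chosen after the data were seen. The other alternatives were planned.

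Numbers of genes rose with the pairing in 9 of the 11 comparisons, and in most also by DESeq2 without the block. The exceptions were cheese against milk at 180 min and the change by 180 min, with 0 genes by edgeR with and without the block (184 and 163 at an unadjusted p under 0.05 without it) and 0 by DESeq2 and voom. At 60 min after milk (136 genes) they were 242 with the participant block, 343 with the visit as a block, 266 with the block and visit number and 274 by DESeq2 with the block. At 180 min after milk (8) they were 117, 244, 138 and 162, and 33 by DESeq2 without the block and 42 by voom with the participant as a random effect. Library totals gave 4 there and the compared groups alone 1. At 60 min after cheese (0 by edgeR, 341 at an unadjusted p under 0.05) they were 53, 100, 61 and 93, 14 by DESeq2 without the block and 21 by voom. At 180 min after cheese (8) they were 167, 255, 179 and 189, then 53 and 109, and 25 at an adjusted p of 0.1. Over both foods at 60 min (138) they were 280, 385, 305 and 294, and 223 by voom. At 180 min (119) they were 397, 607, 437 and 400, 198 by DESeq2 without the block and 327 by voom.

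Between foods at 0 min (0 by edgeR, 388 at an unadjusted p under 0.05) the block gave 2 genes, the block with visit number 4 and DESeq2 with the block 15. At 60 min (5) they gave 122, 138 and 146, DESeq2 without the block 80 and voom 103. Library totals gave 2, no filter 2, the compared groups alone 0 and an adjusted p of 0.1 45. The change by 60 min (0 by edgeR, 272 at an unadjusted p under 0.05) had 83 genes with the participant block, 94 with the visit block, 85 with visit number, 97 and 36 by DESeq2 with and without the block, and 22 by voom. The participant block lowered the common biological coefficient of variation from 0.218 to 0.132. For the visit block, the other tools, library totals, filters and groups the cause was not tested.

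Leaving out 1 participant gave 95 to 129 genes at 60 min and 1 to 13 at 180 min after milk, and 0 and 1 to 53 after cheese. Over both foods it gave 96 to 132 and 16 to 141, between foods at 60 min 0 to 79, and in the change by 60 min 0 to 8. Apart from 60 min after cheese, where each count was 0 by edgeR, the highest came without replicate D. For FOS, cheese vs milk at 60 min, leaving out 1 participant gave log2 values from -4.17 without replicate D (adjusted p = 0.0487) to 4.78 without replicate A, against 2.0 with all 4. For EGR1, cheese vs milk at 60 min, they ran from -3.43 without replicate D (adjusted p = 0.0236) to 3.43 without replicate A, against 1.68. One library of each food held most of these counts.

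Of the 61 list calls, 4 held with an estimated correlation and 12 with the block and an estimated correlation. The 8 regained were the ribosomal proteins (adjusted p = 0.0192, 0.0345 and 0.0403) and TOP messages (0.0112, 0.0146 and 0.0192) at 60 and 180 min after cheese and at 180 min over both foods, and the ribosomal proteins between foods at 60 min (0.0112) and in the change by 60 min (0.0112). Fry gave 5 directional and 24 mixed calls.

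Without each participant in turn, 33 of the 61 list calls passed every time in the same direction. Without replicate D, 47 were called, and 3 others changed direction and no longer passed: immediate early genes at 60 min (adjusted p = 0.95) and the matrix at 180 min (0.782) after cheese, and oxidative phosphorylation between foods at 180 min (0.618). The matrix calls at 60 min after cheese (0.945), over both foods at 60 and 180 min (0.812 and 0.238) and between foods at 0 min (0.816), and inflammation at 180 min after cheese (0.309), also ended without D. Without replicate C the milk calls at 180 min of leukocyte markers (0.961), inflammation (0.0603) and immediate early genes (0.0625) ended, as did leukocyte markers between foods at 0 min (0.238), immediate early genes over both foods at 180 min (0.0616) and the ribosomal proteins in the change by 180 min (0.92). Another 14 calls ended without at least 1 participant (highest adjusted p in brackets). After milk at 60 min this was the immediate early list (0.622). After cheese it was the fast fibre (0.0818), sarcomere (0.0946) and smooth muscle (0.497) lists at 60 min and the clock (0.201) at 180 min, and over both foods the clock at 180 min (0.156). Between foods these were the ribosomal proteins (0.896) and smooth muscle (0.511) at 0 min, oxidative phosphorylation (0.0857) and leukocyte markers (0.331) at 60 min and the sarcomere (0.155) at 180 min. In the change by 60 min they were the sarcomere (0.318) and smooth muscle (0.177) lists, and in the change by 180 min oxidative phosphorylation (0.637).

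The correlation of the foods' changes across genes went from 0.35 to 0.49 at 60 min and from 0.40 to 0.54 at 180 min under the stricter filter, which drops the least precise genes, and without 1 participant ran from 0.24 to 0.31 and 0.27 to 0.35. Over the named genes' values under all settings, 7849 kept their sign and stayed called or stayed uncalled, whatever their size. With the sign kept, 815 passed the threshold newly and 242 no longer passed. Another 182 changed sign without a call in either fit, and 2 changed sign with a call in 1 or both fits. Size factors of the DESeq2 type, the robust fit and leaving out haemoglobin and mitochondrial genes left each count of genes within 1.5 times. The last of these tested 10168 genes in place of 10170, so it had little to remove and could hardly change a count. Thinned to the smallest total, the counts at 60 min after milk were 127 without and 222 with the block, and the change by 60 min had 68 with it.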

Other observations

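The comparisons of 180 with 60 min were chosen after the data were seen. From 60 to 180 min after milk 5 genes rose and 97 fell by edgeR, and 25 and 200 with the participant block. Of the 77 ribosomal protein genes 63 fell (median -1.19, camera adjusted p = 1.89e-132, adjusted p = 0.0368 with an estimated correlation), 75 when adjusted over the list alone. The TOP messages followed with 9 of 27 down and 17 over the list alone (median -0.60, camera adjusted p = 1.21e-22, adjusted p = 0.109 with an estimated correlation). After cheese ARID5B alone fell by edgeR, and with the block 1 gene rose and 9 fell. The ribosomal protein share of counts was 0.663% at 60 min and 0.709% at 180 min there.

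Over the same interval, the change differed between the foods for the ribosomal proteins by a median of 1.32 (cheese minus milk), with 74 of 77 past the threshold over the list alone and 73 with the participant block (camera adjusted p = 1.34e-117, adjusted p = 0.0368 with an estimated correlation). Over all genes edgeR called 0, with 330 at an unadjusted p under 0.05, and the block gave 105 higher and 4 lower. Immediate early genes had a median of -1.17 from 60 to 180 min after milk and -1.40 after cheese, and adjusted p = 0.497 and adjusted p = 0.39 with an estimated correlation. After cheese 1 library at 60 min held 0.293% of its counts on this list, against at most 0.0583% in the others.

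Camera called several lists in none of the 11 planned comparisons. Their medians at 60 and 180 min over both foods were 0.00 and -0.03 for translation initiation control and mTORC1, -0.03 and -0.10 for amino acid transport and ATF4, and 0.02 and -0.11 for atrophy and FOXO targets. Autophagy and lysosome had -0.02 and 0.02, the proteasome 0.01 and 0.03, the insulin response 0.05 and 0.07, and fatty acid oxidation and PPAR targets 0.00 and 0.05. Cholesterol and fatty acid synthesis had 0.05 and -0.02, myogenic regulation -0.10 and -0.04, metallothioneins -0.01 and 0.31, and heat shock 0.01 and -0.05. Endothelial markers had -0.04 and 0.05, adipocyte markers -0.14 and -0.16, and nerve, Schwann cell and keratinocyte markers -0.01 and -0.04. Another 2 lists had fewer than 3 members in the tested genes.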
